A study of Homo sapiens with 40 samples.

How the data were processed

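RNA from MCF 10A cells, a non-tumorigenic human mammary epithelial line, was sequenced in 40 libraries that fall into 10 groups of 4. Per the labels' protocols, the cells were seeded at 30% confluency on fibronectin and cultured, and doxycycline at 1 µg/ml was given for 24 h to induce either SUN1L-KDEL, used to disrupt the LINC complex, or GFP-KDEL as the control, before the flasks went onto a 3-D clinostat. Per the labels' protocols, RNA was extracted with the RNeasy Micro kit and libraries were made with the TruSeq Stranded Total RNA HT kit. The extraction text speaks of blood mononuclear cells while all other labels name MCF 10A cells. Each label also gives an experiment number (1 or 2) and a donor number (1 or 2), and the 4 replicates of a group are the 4 combinations. Nothing says what a donor is in a cell line or that libraries of 1 experiment came from separate cultures, so p-values measure the spread between these libraries, part of which may be technical.

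The authors deposited a table of whole read counts per gene symbol, with no normalization. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p2, Subread and edgeR were used with genome build GRCh38. The gene annotation and the strand setting of the counting are not given in the sources used here. The authors also deposited a table of log2 values for 23479 genes. Recomputing log2 CPM (counts scaled to the library total) from the deposited counts with TMM factors and a prior count of 0.25 gave those values to within 4.97e-14, and the 23479 genes were those with a read in at least 1 library. All tests used the counts, and the log2 table served only for this check. Every per-sample column was matched to a sample by its name.

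Count totals ran from 22928509 to 29156358 reads per library, and the 10 most abundant genes took 7.75% to 11.5% of the counts. Of 33121 genes in the table, 14198 passed edgeR's filterByExpr and were tested. A chi-square comparison of the counts of every pair of replicates, over genes with at least 10 reads, gave at least 2.65 per degree of freedom, so no pair differed as little as counting noise alone. This does not show that the libraries came from separate cultures, and each was counted as 1 replicate.

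Differences were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, robust dispersion estimates, all 40 libraries in 1 fit, a mean per group and a term for experiment. The common biological coefficient of variation was 6.79%, and the experiment term passed the threshold for 1136 genes. Adjusted p-values are Benjamini-Hochberg values over the genes tested, and a gene passed the threshold at an adjusted p under 0.05. Where genes at an unadjusted p under 0.05 are counted, a share of about 0.05 of the genes tested would reach it with no change at all. Fold changes are log2 values with their standard errors. The deviations from the group means of libraries with the same combination of experiment and donor, in simulated microgravity and in 1G, were checked for pairing. In SUN1L-KDEL cells at 20 h all 4 pairs correlated above 0.1 (0.193 to 0.296). Libraries of these groups with different numbers were not compared. A shared experiment or a shared range of sequencing sample-sheet numbers could give the same values, so pairing is not shown. At 2 h the correlations in SUN1L-KDEL cells ran from 0.0121 to 0.304, with 3 of 4 above 0.1, and in GFP-KDEL cells they ran from -0.0988 to 0.29 at 2 h and from -0.161 to 0.235 at 20 h. The mean over all 180 pairs of libraries with the same number, across the 10 groups, was 0.0293. It was 0.023 over pairs of the same experiment and 0.179 over pairs from the same range of sample-sheet numbers. The 12 comparisons were simulated microgravity against 1G in each line at 2 h and at 20 h, the difference of these responses between lines at each time, the difference of the responses between times in each line, the lines against each other in 1G at 0 h and over all 3 times, and 2 h and 20 h against 0 h in 1G as a mean over both lines.

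Lists of 44 pathways, complexes and cell types (1015 entries, of which 1002 matched a gene in the table) were tested with camera from limma 3.58.1 at a preset correlation between genes of 0.01, with adjustment over the 42 lists that had at least 5 tested members. The test was repeated with the correlation estimated from the data, and fry was run beside it. None of the 13 mitochondrially encoded genes was among the table's symbols and 3 of 12 endothelial markers passed the filter, so these lists were not tested. Counts of list members past the threshold are given over all genes tested and adjusted over the list alone. Where a list that passed is given with 1 adjusted p, it is the value at the preset correlation, and the list also passed with the estimated one. Camera compares a list with the other genes, so a list can pass with no member past the threshold.

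The lists, the design, the alternatives chosen with it and the rule for named genes were fixed before the data were examined. The rule takes genes with a symbol, a mean log2 CPM of at least 1, an adjusted p under 0.05 and the same sign in both experiments: the 8 largest increases and 8 largest decreases for each gravity response, 6 and 6 for the other comparisons and 3 and 3 for the differences between times. It adds up to 4 members with the smallest p of each list that passed or had at least 3 members past the threshold, the 5 genes with the smallest p where fewer than 5 passed, and a panel reported whatever its values (SUN1, SUN2, SYNE1, SYNE2, SYNE3, LMNA, LMNB1, EMD, CYR61, CTGF and ANKRD1). The text gives a selection of these genes. Coordinates and strands come from GENCODE 29 on GRCh38, to which 13201 of the tested genes matched by symbol. Of the tested genes, 5311 have an exon that overlaps an exon of another gene on the opposite strand. Because the strand setting is not given, reads of such a gene and of its partner may be mixed, and these genes are named as overlapping.

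The pipeline was tested on simulated counts with 200 changed genes. They were drawn from 1 mean per gene over all 40 libraries, with the real library sizes and dispersions. The draws held no effect of experiment and no correlation between genes. For the GFP-KDEL response at 2 h, 33.3% of genes changed 1.2-fold, 71.6% of those changed 1.5-fold and 81.5% of those changed 2-fold were recovered among 14085 genes tested. In the simulation of the SUN1L-KDEL response at 2 h these shares were 44.8%, 75.8% and 78.8% of 14083 genes tested, and for the difference between lines at 20 h 23.9%, 52.2% and 80.3% of 14088. A list shifted 1.1-fold as a whole was recovered in the simulated SUN1L-KDEL response at 2 h and was not called in the simulated GFP-KDEL response, in which it had not been shifted. This was at the preset correlation with genes drawn independently, so it does not show how the list test does when genes are correlated.

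The alternatives chosen with the design were size factors and the Wald test from DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a stricter filter (CPM of at least 1 in at least 20 libraries), the combination of experiment and donor as a block, no experiment term, a fit of the compared libraries alone, each experiment alone and each library left out in turn. Alternatives added after the data were seen were ranges of the sequencing sample-sheet numbers as a term, a GC offset per library, 2 surrogate variables from sva 3.50.0, and the tests without overlapping genes. Each comparison was also recomputed over other splits of its libraries (all 35 splits of 8 libraries, otherwise 100 drawn with a fixed seed).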

Results

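Gene expression was measured by total RNA sequencing in MCF 10A cells, a non-tumorigenic line of human mammary epithelium, that carried a doxycycline-inducible SUN1L-KDEL or GFP-KDEL construct. SUN1L-KDEL disrupts the LINC complex, the set of SUN and nesprin proteins that spans the nuclear envelope and links the nuclear lamina to the cytoskeleton, and GFP-KDEL served as the control. Cells of each line were collected at 0 h in normal gravity (1G) and after 2 h and 20 h in 1G or on a 3-D clinostat, which rotates the flask to simulate microgravity. The 10 groups held 4 libraries each, 2 from each of 2 experiments. Changes are given as log2 fold change ± standard error from all 40 libraries, and levels as CPM (counts scaled to the library total), mean ± SD of 4 libraries. Genes given as the largest changes are the largest among those the naming rule admits, with a gene symbol other than a clone name, a mean log2 CPM of at least 1 and the same sign in both experiments. Larger changes of genes at lower levels are left unnamed. The series asks, by its title, whether the response to simulated microgravity depends on the LINC complex.

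SUN1 itself (chromosome 7, 816615 to 896435, plus strand; GRCh38) stood at 99.5 ± 4.23 CPM in GFP-KDEL and 104 ± 5.54 CPM in SUN1L-KDEL cells at 0 h (SD, n = 4), a difference of 0.06 ± 0.04 on the log2 scale (adjusted p = 0.46). Group means stayed between 99.5 and 110.1 CPM across the 10 groups. The labels do not say which part of SUN1 the construct holds, and SUN1 overlaps an exon on the opposite strand, so this level is no check of induction. Over the 3 times in 1G, SUN2 was 0.09 ± 0.03 higher in SUN1L-KDEL cells (adjusted p = 0.0269; overlapping). LMNA (0.03 ± 0.03), LMNB1 (-0.04 ± 0.02), EMD (-0.01 ± 0.05), SYNE1 (0.03 ± 0.04; overlapping), SYNE2 (0.03 ± 0.04) and SYNE3 (0.03 ± 0.09) did not pass the threshold. The list of the LINC complex and nuclear lamina had 2 of its 23 tested members higher and 2 lower (adjusted p = 0.885, and adjusted p = 0.882 with an estimated correlation). Adjusted over the list alone, 2 were higher and 4 lower.

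Before any clinostat exposure, SUN1L-KDEL cells had higher levels of endoplasmic reticulum (ER) chaperones and ATF4 targets than GFP-KDEL cells. AGR2, a protein disulfide isomerase of the ER (chromosome 7, 16791811 to 16833433, minus strand), stood at 21.1 ± 1.56 CPM against 4.82 ± 0.425 CPM (SD, n = 4), a log2 difference of 2.13 ± 0.10 (adjusted p = 4.47e-19). IGFBP3, which binds insulin-like growth factors (1.37 ± 0.09), CCND2 (cyclin D2, 1.38 ± 0.18), PPL (periplakin, 1.14 ± 0.20) and ARSD (1.13 ± 0.16) were the next largest increases among genes at a mean log2 CPM of at least 1. The basal keratin KRT14 followed (1.09 ± 0.13). The largest decreases at that level were in ALB (albumin, -1.19 ± 0.12), RAMP1 (-1.17 ± 0.19), LPXN (-0.95 ± 0.10), ZNF320 (-0.92 ± 0.09), the inflammasome sensor NLRP3 (-0.89 ± 0.13) and CTSS (cathepsin S, -0.83 ± 0.18). Of 26 tested genes of the unfolded protein response and ER chaperones, 17 were higher and 0 lower, and 21 were higher when adjusted over the list alone (adjusted p = 9.99e-30). They included CRELD2 (0.63), SEL1L (0.52) and PDIA4 (0.43). Of 24 targets of ATF4 and the integrated stress response, 6 were higher and 10 when adjusted over the list alone, with ASNS (0.66), WARS (0.31) and PSAT1 (0.25) as examples (adjusted p = 9.57e-09). Of 31 genes of G2/M and mitosis, 9 were lower, and 19 when adjusted over the list alone, among them BUB1 (-0.20), CCNA2 (-0.18) and BIRC5 (-0.17). This list passed at the preset correlation only (adjusted p = 1.41e-08, and adjusted p = 0.0685 with an estimated correlation). Fibroblast markers moved with the line as well, with 2 of 6 higher (DCN at 1.01 and MFAP5 at 0.82; adjusted p = 1.6e-05, and adjusted p = 0.0543 with an estimated correlation). Adjusted over the list alone, 4 were higher. In all, edgeR called 435 genes higher and 365 lower of 14198, with 451 calls in experiment 1 alone and 380 in experiment 2 alone, and 512 without replicate 2 of the GFP-KDEL group at 0 h. There were 1278 with 2 surrogate variables and 512 without overlapping genes. The labels do not say how many lines were made per construct, so line and construct go together here. CCND2, ARSD, CRELD2, WARS, CCNA2 and MFAP5 overlap genes on the opposite strand.

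Averaged over 0, 2 and 20 h in 1G, the lines differed in 1213 genes higher and 960 lower in SUN1L-KDEL cells. AGR2 (2.18 ± 0.06), IGFBP3 (1.56 ± 0.05), SERPINA3 (1.08 ± 0.09), ZNF518B (1.06 ± 0.05) and KRT14 (1.05 ± 0.08) were among the largest increases at a mean log2 CPM of at least 1. ALB (-1.23 ± 0.07), RAMP1 (-1.20 ± 0.10) and MPP4 (-0.91 ± 0.11) were among the largest decreases. Members of the unfolded protein response were higher in 21 of 26 cases, 22 when adjusted over the list alone (adjusted p = 7.26e-47). ATF4 targets were higher in 18 of 24, 19 adjusted over the list alone (adjusted p = 2.76e-15). Fibroblast markers were higher in 4 of 6 cases, 5 adjusted over the list alone (adjusted p = 1.16e-07), namely DCN (0.97), MFAP5 (0.77), FAP (0.43) and FBLN1 (0.27), of which MFAP5 and FAP overlap other genes. Luminal markers passed the list test with 2 of 11 higher, 3 higher and 1 lower when adjusted over the list alone (adjusted p = 9.87e-07), and AGR2 is itself 1 of the 2. Targets of glucocorticoids had 5 of 16 higher and 1 lower, the same numbers adjusted over the list alone (adjusted p = 0.0008), with KLF9 (0.35) and GLUL (0.21) among those higher. Experiment 1 alone gave 974 calls and experiment 2 alone 1603, and 1385 were called without overlapping genes.

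**Figure D1:**
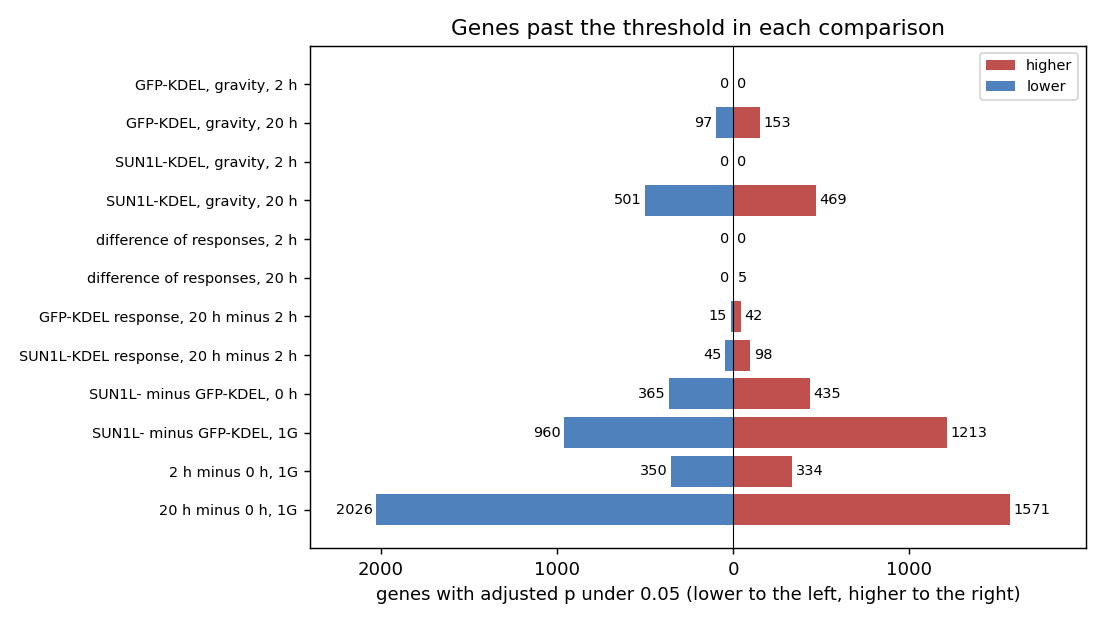
Genes with an adjusted p under 0.05 in each of the 12 comparisons (edgeR, 14198 genes tested, 4 libraries per group), with higher genes drawn to the right and lower genes to the left of 0 on the axis of gene counts. The gravity responses count 0 genes at 2 h in both lines, 250 at 20 h in GFP-KDEL cells and 970 at 20 h in SUN1L-KDEL cells.

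In GFP-KDEL cells, 20 h of simulated microgravity raised ER chaperones, heat shock genes and targets of TGF-beta and SMAD signalling, and lowered the enzyme genes CYP1A1, CYP1B1 and ALDH3A1 and the plakin PPL. Among genes at a mean log2 CPM of at least 1, the largest increases were in CDKN1C, an inhibitor of cyclin-dependent kinases (0.78 ± 0.17), the matrix protein POSTN (0.75 ± 0.18), IGFBP3 (0.71 ± 0.09) and the apoptosis inhibitor BIRC3 (0.69 ± 0.11). They were followed by involucrin (IVL, 0.69 ± 0.19), the immunoproteasome subunit PSMB9 (0.67 ± 0.17), tropomyosin 1 (TPM1, 0.61 ± 0.09) and CRELD1 (0.61 ± 0.10). BIRC3 (chromosome 11, 102317450 to 102339403, plus strand) went from 184 ± 39.9 CPM in 1G to 296 ± 44.9 CPM (SD, n = 4; adjusted p = 0.000317). IGFBP3 (chromosome 7, 45912245 to 45921874, minus strand) went from 7.96 ± 0.962 to 13 ± 1.19 CPM (adjusted p = 3.17e-06). The largest decreases at that level were in the cytochrome P450 genes CYP1A1 (-1.21 ± 0.29) and CYP1B1 (-0.76 ± 0.14), PPL (-0.97 ± 0.21) and the aldehyde dehydrogenase ALDH3A1 (-0.95 ± 0.18). FAT2 (-0.74 ± 0.16), the ganglioside synthase ST3GAL5 (-0.64 ± 0.11), the transcription factor E2F2 (-0.58 ± 0.15) and the DNA damage-binding gene DDB2 (-0.55 ± 0.07, adjusted p = 4.65e-06) came next. CYP1A1 (chromosome 15, 74719542 to 74725610, minus strand) stood at 5.55 ± 0.697 CPM in 1G and 2.39 ± 0.735 CPM in simulated microgravity (SD, n = 4; adjusted p = 0.0234). Of the panel, ANKRD1 rose by 0.60 ± 0.17 (adjusted p = 0.0499) and the nesprin gene SYNE2 changed by -0.26 ± 0.06 (adjusted p = 0.0184). LMNA (-0.05 ± 0.05), LMNB1 (-0.11 ± 0.04), SUN1 (-0.01 ± 0.04), CYR61 (0.13 ± 0.10) and CTGF (0.03 ± 0.13) did not pass.

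Among the lists in GFP-KDEL cells at 20 h, 9 of 26 unfolded protein response genes rose and 0 fell, 10 when adjusted over the list alone (adjusted p = 3.02e-13). Examples were MANF (0.30), DNAJB11 (0.18) and PDIA6 (0.16). TGF-beta and SMAD targets rose in 4 of 19 cases, with 13 higher and 1 lower adjusted over the list alone (adjusted p = 5.47e-12), among them ID3 (0.41) and ID1 (0.30). Heat shock genes rose in 3 of 19 cases, 11 adjusted over the list alone (adjusted p = 3.8e-11), including CHORDC1 (0.24) and HSPH1 (0.21). These 3 lists are the ones that passed with an estimated correlation as well. At the preset correlation alone, NF-kB and inflammatory genes passed with 3 of 22 higher, 8 adjusted over the list alone (adjusted p = 5.22e-07, and adjusted p = 0.0623 with an estimated correlation). Higher there were BIRC3 (0.69), CCL20 (0.45) and IL1B (0.31). SRF and MRTF targets passed likewise with 2 of 24 higher, 4 adjusted over the list alone (adjusted p = 0.000315, and adjusted p = 0.153 with an estimated correlation). Genes of G1/S and DNA replication passed the same way with 2 of 27 lower, E2F2 and ORC1 (-0.28), and also 2 adjusted over the list alone (adjusted p = 0.000347, and adjusted p = 0.188 with an estimated correlation). So did G2/M genes with 0 of 31 past the threshold in edgeR or adjusted over the list alone (adjusted p = 0.000365, and adjusted p = 0.241 with an estimated correlation). Fibroblast markers had 1 of 6 higher (POSTN), 2 adjusted over the list alone (adjusted p = 0.0271, and adjusted p = 0.269 with an estimated correlation). The comparison gave 153 higher and 97 lower genes with a median change of 1.21-fold, 128 calls in experiment 1 alone and 20 in experiment 2 alone. The number ranges of the sample sheet as a term gave 469 calls, 2 surrogate variables 478, no filter on low counts 399, a fit of the compared libraries alone 157, and the genes without overlaps 158. There were 149, 162 and 151 calls without replicates 1 and 2 in simulated microgravity and replicate 3 in 1G, in that order. PSMB9, TPM1, CYP1B1, ALDH3A1, FAT2, SUN1, CTGF, CHORDC1, DNAJB11 and PDIA6 overlap genes on the opposite strand.

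In SUN1L-KDEL cells, the same 20 h raised ER chaperones, ATF4 targets and inflammatory genes and lowered genes of DNA replication, mitosis, DNA repair, and ribosome biogenesis, and the lamin genes LMNB1 and LMNA. At a mean log2 CPM of at least 1, the largest increases were in BIRC3 (0.92 ± 0.11), the kinase STK32A (0.90 ± 0.17), AGR2 (0.88 ± 0.09) and the chemokine IL8 (0.87 ± 0.23). MPP4 (0.85 ± 0.21), INHBA, a subunit of activin (0.79 ± 0.09), CRELD1 (0.78 ± 0.09) and EFR3B (0.77 ± 0.17) came next. BIRC3 went from 208 ± 24.8 to 396 ± 41.6 CPM (SD, n = 4; adjusted p = 2.25e-06) and INHBA from 10.9 ± 1.89 to 18.8 ± 0.84 CPM (adjusted p = 8.7e-08). Decreases at that level were led by MRPL23, a mitochondrial ribosomal protein (-1.45 ± 0.35), KCTD4 (-0.63 ± 0.16), FAM201A (-0.62 ± 0.18) and NUDT8 (-0.61 ± 0.18). They were followed by ACADS, an acyl-CoA dehydrogenase (-0.55 ± 0.14), PP7080 (-0.53 ± 0.08), SAPCD2 (-0.51 ± 0.11) and PDLIM2 (-0.51 ± 0.14). MRPL23 varied widely between the 1G libraries, at 24.7 ± 12.9 CPM, against 9.07 ± 1.01 CPM in simulated microgravity (SD, n = 4; adjusted p = 0.00853). The lamin genes LMNB1 (-0.24 ± 0.04, adjusted p = 0.000172) and LMNA (-0.23 ± 0.05, adjusted p = 0.00403) fell, as did the lamin B receptor LBR (-0.20 ± 0.04) and TMPO (-0.19 ± 0.04). SUN1 (-0.03 ± 0.04), SUN2 (-0.12 ± 0.05), EMD (0.02 ± 0.09), CYR61 (0.07 ± 0.10), CTGF (0.31 ± 0.13) and ANKRD1 (0.22 ± 0.14) did not pass the threshold.

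Of the 26 unfolded protein response genes, 17 rose in SUN1L-KDEL cells at 20 h and 0 fell, 23 adjusted over the list alone (adjusted p = 1.26e-38). Among them were PDIA4 (0.45), HSP90B1 (0.43) and DNAJC3 (0.40). ATF4 targets rose in 8 of 24 cases and fell in 1, 9 and 1 adjusted over the list alone (adjusted p = 1.1e-06). They included DDIT3 (0.44), the asparagine synthetase ASNS (0.40) and the tryptophanyl-tRNA synthetase WARS (0.31). Inflammatory genes rose in 7 of 22 cases, 10 adjusted over the list alone (adjusted p = 5.82e-09), with IL1A (0.47) and IL1B (0.45) beside BIRC3 and IL8. TGF-beta and SMAD targets rose in 4 of 19, 8 adjusted over the list alone (adjusted p = 4.42e-07). Cell cycle genes fell in 22 of 31 cases for G2/M and mitosis, 27 adjusted over the list alone (adjusted p = 3.98e-24). They fell in 18 of 27 for G1/S and DNA replication, 22 adjusted over the list alone (adjusted p = 9.64e-20). The first included KIF2C (-0.31), CCNA2 (-0.25) and BIRC5 (-0.22) and the second MCM7 (-0.33), ORC1 (-0.32) and MCM6 (-0.23). DNA repair genes fell in 8 of 24 cases, 14 adjusted over the list alone (adjusted p = 6.35e-08). Also lower were ribosome biogenesis genes in 10 of 24, 13 adjusted over the list alone (adjusted p = 5.82e-09). Matrix proteases passed with 1 of 17 higher, PLAUR (0.35), also 1 adjusted over the list alone (adjusted p = 0.00393). Hypoxia targets passed with 5 of 23 higher and 2 lower, 6 and 2 adjusted over the list alone (adjusted p = 0.00726). The LINC and lamina list had 1 of 23 higher and 6 lower, and 2 and 8 adjusted over the list alone. Its mean was -0.05, its median 0.01, and it did not pass (adjusted p = 0.0933, and adjusted p = 0.141 with an estimated correlation).

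Passing in SUN1L-KDEL cells at the preset correlation only were integrins and focal adhesion genes (4 of 24 higher, 6 adjusted over the list alone, adjusted p = 0.00114, and adjusted p = 0.072 with an estimated correlation). Higher there were ITGA2 (0.45) and ITGB6 (0.25). Nuclear pore genes (4 of 28 lower, 7 adjusted over the list alone, adjusted p = 0.00138, and adjusted p = 0.0899 with an estimated correlation) passed the same way. So did replication-dependent histones (3 of 17 lower, 5 adjusted over the list alone, adjusted p = 0.0023, and adjusted p = 0.427 with an estimated correlation). edgeR called 469 genes higher and 501 lower, with a median change of 1.18-fold, and 158 in experiment 1 alone and 169 in experiment 2 alone. Without replicate 2 in simulated microgravity 590 genes were called, without replicate 3 in 1G 622, and without overlapping genes 592. MRPL23, FAM201A, PP7080, SAPCD2, TMPO, SUN1, SUN2, CTGF, HSP90B1, DDIT3, WARS, KIF2C, CCNA2 and MCM7 overlap genes on the opposite strand.

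**Figure D2:**
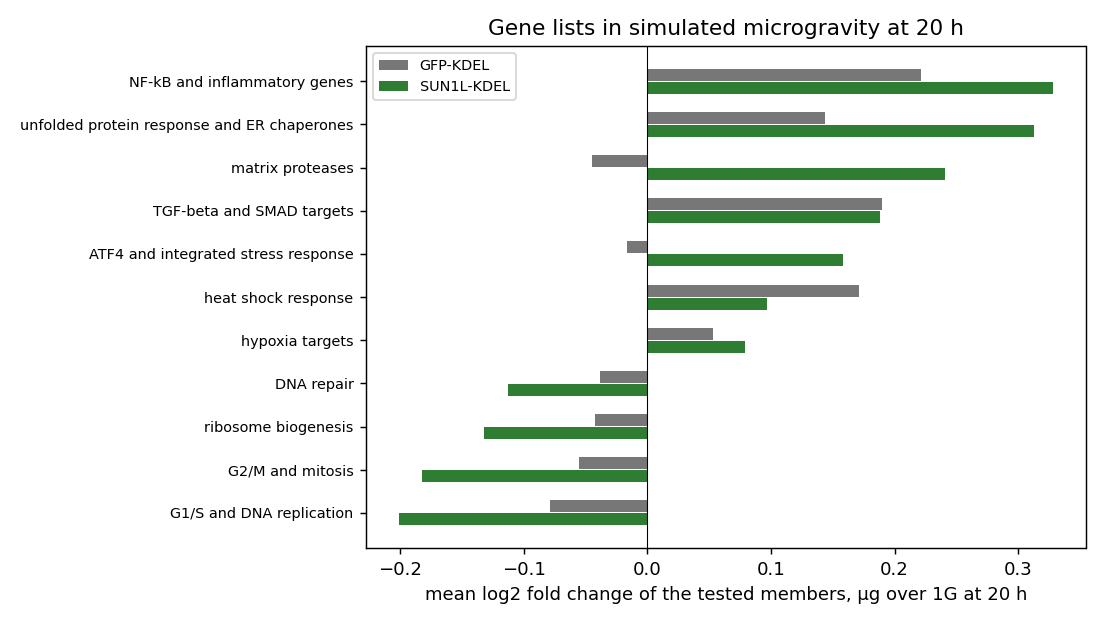
Mean log2 fold change, simulated microgravity over 1G at 20 h, of the tested members of 11 gene lists in GFP-KDEL (grey) and SUN1L-KDEL cells (green), as bars from 0 without error bars. The unfolded protein response list stands at 0.14 and 0.31, and the G2/M list at -0.06 and -0.18.

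Both lines changed many of the same genes at 20 h. Past the threshold in both were 94 higher genes, where independent lists of these sizes would share 5.05, and 54 lower genes, where 3.42 would be shared, with 1 gene past the threshold in opposite directions. BIRC3 and CRELD1 were among the shared higher genes, and DDB2 (-0.55 and -0.47) and ORC1 (-0.28 and -0.32) among the shared lower ones. Of the 250 genes called in GFP-KDEL cells, 241 had the same sign in SUN1L-KDEL cells, and of the 970 called there 889 had the same sign in GFP-KDEL cells. The correlation of log2 changes across all 14198 genes was 0.292, with genes not being independent replicates, and the compared groups share no library. Without the filter on low counts it was 0.0363. Shared genes numbered 226 with the number ranges as a term, 255 with 2 surrogate variables and 95 without overlapping genes. Within experiments, the shared genes numbered 39 in experiment 1 alone and 15 in experiment 2 alone, with correlations of 0.265 and 0.198.

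**Figure D3:**
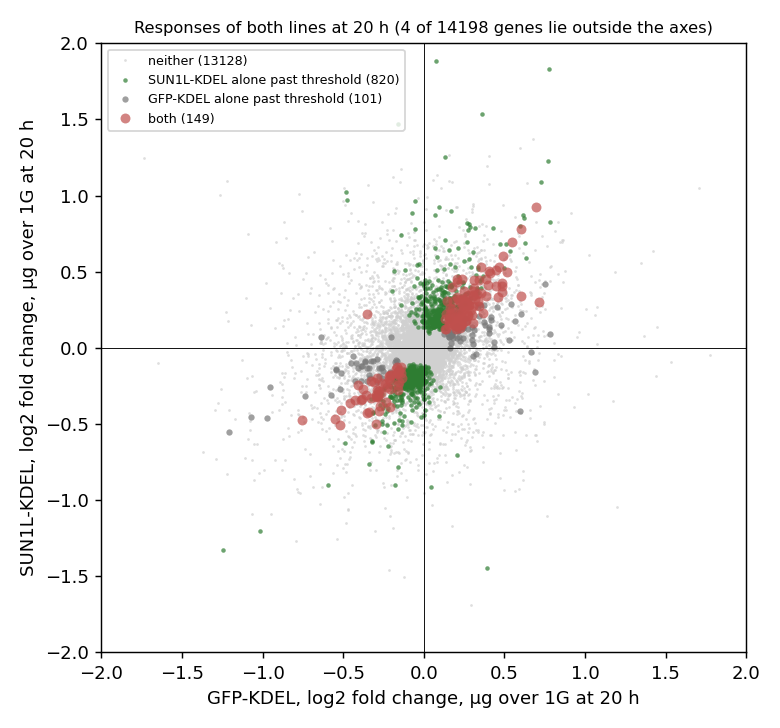
Log2 fold change, simulated microgravity over 1G at 20 h, of each tested gene in GFP-KDEL cells (horizontal axis) and SUN1L-KDEL cells (vertical axis), coloured by the line or lines in which it passed the threshold, with 4 of 14198 genes outside the axes. The 149 genes past the threshold in both lines lie in the upper right and lower left, except for 1.

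Tested as a difference between lines, the 20 h response was more positive in SUN1L-KDEL cells for 5 genes, which take part in protein handling in the ER or in amino acid stress. They included AGR2 (0.95 ± 0.16), TRIB3, a pseudokinase induced by ATF4 (0.58 ± 0.10; chromosome 20, 362835 to 397559, plus strand) and SEL1L, an adaptor of ER-associated degradation (0.41 ± 0.07; chromosome 14, 81471549 to 81533861, minus strand). The others were ASNS (0.40 ± 0.07; chromosome 7, 97852118 to 97872542, minus strand) and WARS (0.29 ± 0.05; chromosome 14, 100333788 to 100376805, minus strand; overlapping). AGR2 went from 13.4 ± 1.13 to 24.7 ± 0.283 CPM in SUN1L-KDEL cells and from 3.29 ± 0.151 to 3.13 ± 0.581 CPM in GFP-KDEL cells (SD, n = 4; adjusted p = 0.0024). TRIB3 moved apart, from 29.6 ± 2.26 to 34.6 ± 1.84 CPM in SUN1L-KDEL and from 27.9 ± 2.55 to 21.9 ± 1.51 CPM in GFP-KDEL cells (adjusted p = 0.00257). SEL1L went from 260.5 ± 12.2 to 350.3 ± 16.3 CPM against 201 ± 4.16 and 203 ± 18.2 CPM in GFP-KDEL cells. ASNS went from 49.2 ± 1.78 to 65.1 ± 2.59 CPM against 35.3 ± 2.06 and 35.4 ± 1.3 CPM (adjusted p = 0.0024 for both). For SUN1 (-0.03 ± 0.06), LMNA (-0.18 ± 0.08), LMNB1 (-0.13 ± 0.06) and SYNE2 (0.13 ± 0.09) the difference of responses did not pass.

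As lists, G2/M and mitosis (0 of 31 past the threshold in edgeR, 6 lower adjusted over the list alone, adjusted p = 1.64e-13) responded more negatively in SUN1L-KDEL cells at 20 h. So did G1/S and DNA replication (0 of 27, 3 lower adjusted over the list alone, adjusted p = 3.06e-10). Unfolded protein response genes (1 of 26 higher, 5 adjusted over the list alone, adjusted p = 1.8e-12) responded more positively. ATF4 targets (3 of 24 higher, 6 adjusted over the list alone, adjusted p = 3.13e-09) and matrix proteases (0 of 17, and 0 adjusted over the list alone, adjusted p = 0.00341) did as well. With the filter on low counts, edgeR called these 5 of 14198 genes, with 903 at an unadjusted p under 0.05, 5 by the DESeq2 test and 7 by limma-voom. Without the filter, where the fit gave no weight to the median gene's own spread, it called 63, of which 25 were higher and 38 lower, the 5 included. Each experiment alone called 0 genes in edgeR, with 941 and 584 at an unadjusted p under 0.05, the first above and the second below the share of 0.05 expected with no change. The log2 difference of AGR2 was 1.16 in experiment 1 and 0.793 in experiment 2 and the other 4 genes were also positive in both.

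**Figure D4:**
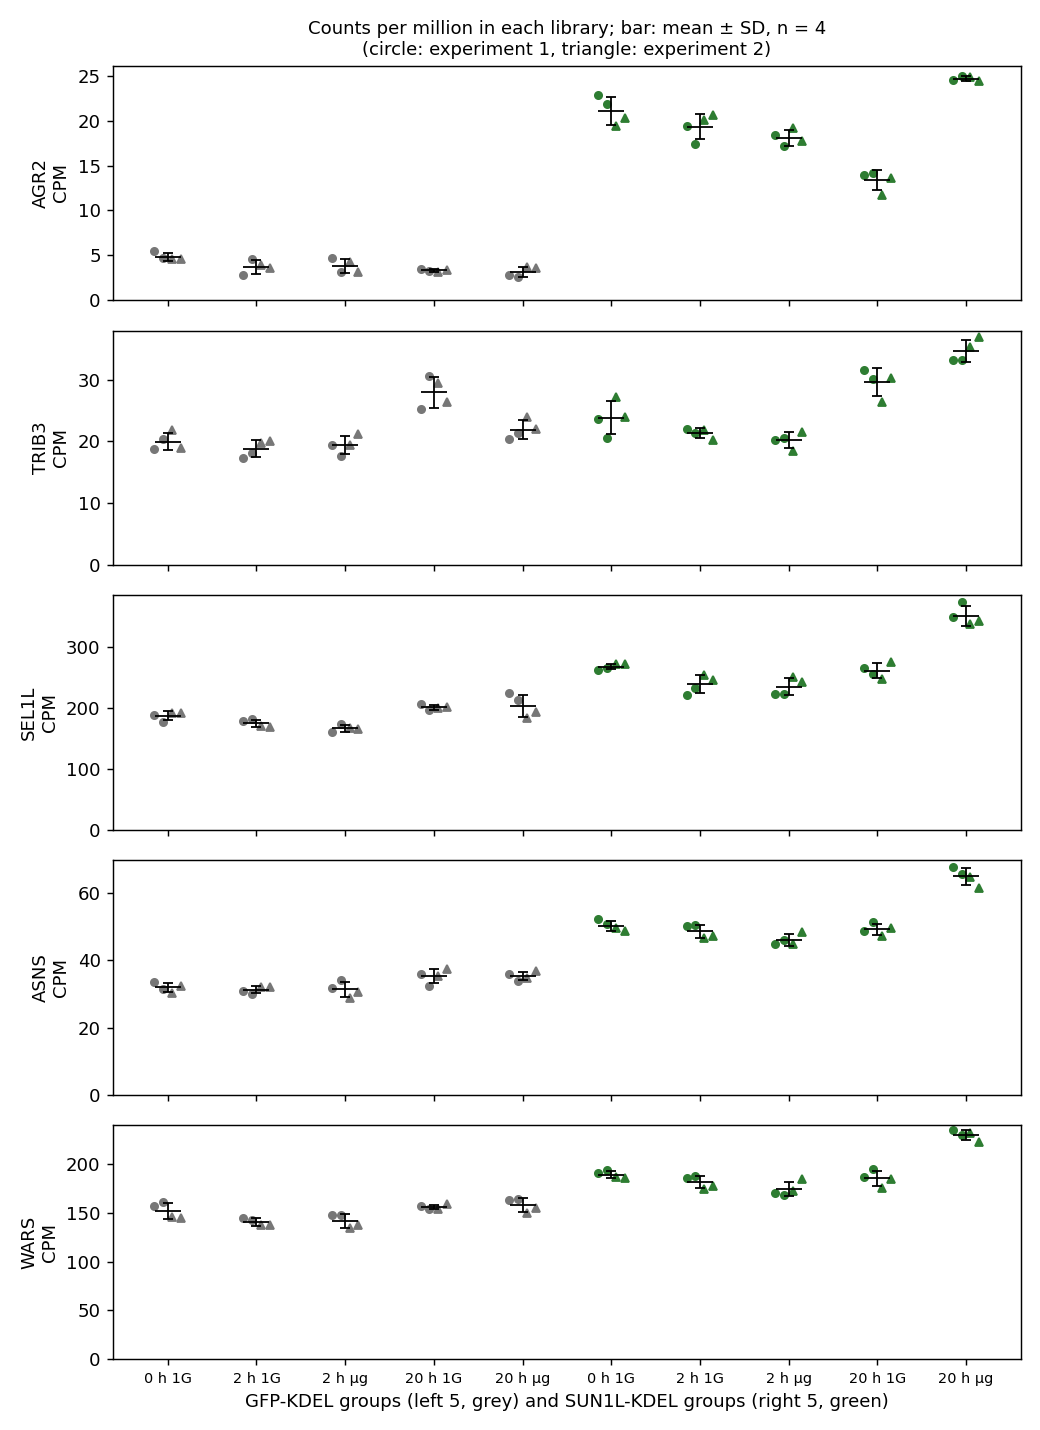
CPM of AGR2, TRIB3, SEL1L, ASNS and WARS in each library (circles for experiment 1, triangles for experiment 2) over the 10 groups, with bars for mean ± SD of 4 libraries. In SUN1L-KDEL cells AGR2 stands at 13.4 ± 1.13 CPM in 1G and 24.7 ± 0.283 CPM in simulated microgravity at 20 h.

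At 2 h, with the filter on low counts, no gene passed the threshold for simulated microgravity in either line. Without it, the fit gave no weight to the median gene's own spread, and edgeR called 23 genes in GFP-KDEL cells, 85 in SUN1L-KDEL cells and 63 for the difference. In GFP-KDEL cells edgeR called 0 of 14198 genes, with 423 at an unadjusted p under 0.05 and 0 by the DESeq2 test and limma-voom. In SUN1L-KDEL cells it called 0, with 1036 at an unadjusted p under 0.05 and 0 by both other tools. A share of about 0.05 of the genes would reach this p with no change, and 423 lies below that share and 1036 above it. At a mean log2 CPM of at least 1, the smallest p in GFP-KDEL cells belonged to PLEKHA8 (-0.24 ± 0.06), GADD45B, a stress-induced gene (0.29 ± 0.09), and ID1 (0.18 ± 0.05). Next were the overlapping genes C15orf65 (0.44 ± 0.13) and ZNF93 (0.35 ± 0.10; adjusted p = 1 for all 5). In SUN1L-KDEL cells they belonged to LINC-PINT (0.44 ± 0.10), FYCO1 (0.34 ± 0.08), IQGAP3 (0.29 ± 0.07), ZFC3H1 (0.24 ± 0.06; overlapping) and KDM3B (0.21 ± 0.05; adjusted p = 0.566 for each). Some lists passed at the preset correlation with 0 members past the threshold in edgeR. In SUN1L-KDEL cells cytosolic ribosomal proteins were lower as a list (1 of 31 lower adjusted over the list alone, adjusted p = 2.78e-13, and adjusted p = 0.385 with an estimated correlation). So were nuclear-encoded genes of oxidative phosphorylation (2 of 30, adjusted p = 4.37e-08, and adjusted p = 0.385 with an estimated correlation). YAP and TAZ targets were higher as a list (0 of 24, adjusted p = 1.03e-05, and adjusted p = 0.159 with an estimated correlation). In GFP-KDEL cells TGF-beta and SMAD targets were higher as a list (1 of 19 adjusted over the list alone, adjusted p = 0.00312, and adjusted p = 0.375 with an estimated correlation). Unfolded protein response genes were lower as a list (0 of 26, adjusted p = 0.00237, and adjusted p = 0.466 with an estimated correlation). No list passed with an estimated correlation at 2 h. The difference of responses between lines at 2 h gave 0 genes in edgeR, 1024 at an unadjusted p under 0.05 and 0 by the other tools. Among the smallest p were those of SLC5A3 (0.37 ± 0.09), PLEKHA8 (0.36 ± 0.09), CISD3 (-0.33 ± 0.09) and HCG18 (0.28 ± 0.07) (adjusted p = 0.567 for each; CISD3 and HCG18 overlapping). Experiment 1 alone called 1 gene in GFP-KDEL cells, 32 in SUN1L-KDEL cells and 39 for the difference. Experiment 2 alone called 0 in each, with 408, 549 and 293 at an unadjusted p under 0.05, all below the share expected with no change. In simulated data, edgeR recovered 33.3% and 44.8% of genes changed 1.2-fold in the GFP-KDEL and SUN1L-KDEL responses at 2 h, and 10.4% for the difference between lines (53.7% at 1.5-fold).

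Between 2 h and 20 h, the response to simulated microgravity grew for ER chaperones in both lines. In GFP-KDEL cells CRELD1 (0.78 ± 0.14), the sialomucin PODXL (0.73 ± 0.16) and the ER co-chaperone DNAJB9 (0.66 ± 0.13) had the largest increases of the response at a mean log2 CPM of at least 1. PPL (-1.29 ± 0.31), E2F2 (-0.95 ± 0.20) and SECTM1 (-0.73 ± 0.16) had the largest decreases. In SUN1L-KDEL cells the largest increases were in AGR2 (0.98 ± 0.13, adjusted p = 1.07e-05), ESM1 (0.96 ± 0.20) and CRELD1 (0.89 ± 0.13) and the largest decreases in FAM201A (-1.01 ± 0.24), PP7080 (-0.62 ± 0.11) and TROAP (-0.52 ± 0.11). Unfolded protein response genes had 5 of 26 with a higher response at 20 h in GFP-KDEL cells, 11 adjusted over the list alone (adjusted p = 9.88e-16). There were 13 in SUN1L-KDEL cells, 20 adjusted over the list alone (adjusted p = 3.34e-45). Heat shock genes passed in GFP-KDEL cells with 2 of 19 higher, 5 adjusted over the list alone (adjusted p = 5.16e-11). In SUN1L-KDEL cells the response of G2/M genes was lower at 20 h in 8 of 31 cases, 21 adjusted over the list alone (adjusted p = 9.67e-20). For G1/S genes it was lower in 4 of 27, 16 adjusted over the list alone (adjusted p = 8.29e-15). For ATF4 targets it was higher in 2 of 24, 6 adjusted over the list alone (adjusted p = 2.51e-08). The totals were 42 higher and 15 lower responses in GFP-KDEL cells (18 calls in experiment 1 alone and 0 in experiment 2 alone, where 707 genes had an unadjusted p under 0.05). They were 98 and 45 in SUN1L-KDEL cells (42 and 3). In GFP-KDEL and SUN1L-KDEL cells, no filter on low counts gave 159 and 284, the number ranges as a term 104 and 250, 2 surrogate variables 101 and 290, and the DESeq2 test 88 and 244. Lower were the counts without an experiment term (32 and 90) and without overlapping genes (37 and 91), and in SUN1L-KDEL cells that from the compared libraries alone (90). Leaving out GFP-KDEL libraries gave 32 without replicate 1 and 35 without replicate 2 in simulated microgravity at 20 h, 36 without replicate 3 in simulated microgravity at 2 h and 30 without replicate 3 in 1G at 20 h. Leaving out SUN1L-KDEL libraries in simulated microgravity gave 77, 76 and 216 without replicates 1, 2 and 3 at 2 h and 88 without replicate 3 at 20 h. DNAJB9, FAM201A, PP7080 and TROAP overlap genes on the opposite strand.

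As a mean over both lines, 684 genes differed from 0 h after 2 h in 1G and 3597 after 20 h. At 2 h, CYP1A1 rose by 5.39 ± 0.32 (adjusted p = 1.12e-13) and CYP1B1 by 4.18 ± 0.13, followed at a mean log2 CPM of at least 1 by the interleukin genes IL24 (2.21 ± 0.17) and IL1B (1.48 ± 0.07). TIPARP (1.22 ± 0.06) and the protease inhibitor SERPINB2 (1.21 ± 0.14) came next. PLD6 (-0.73 ± 0.07), ADAMTS1 (-0.69 ± 0.11), the clock-controlled gene TEF (-0.59 ± 0.12), CXCL1 (-0.59 ± 0.15), PRICKLE1 (-0.56 ± 0.09) and CITED2 (-0.55 ± 0.10) fell. CYP1A1 stood at 0.196 ± 0.0947 CPM at 0 h and 6.59 ± 4 CPM at 2 h in GFP-KDEL cells (SD, n = 4). Inflammatory genes rose in 5 of 22 cases and fell in 1, 6 and 1 adjusted over the list alone (adjusted p = 1.08e-20). Notch, Wnt and EGF targets rose in 5 of 20 and fell in 2, also 5 and 2 adjusted over the list alone (adjusted p = 0.000264). They included EPGN (0.79), EREG (0.35) and HES1 (-0.46). Genes of cholesterol and fatty acid synthesis fell in 8 of 29 cases, 17 adjusted over the list alone, at the preset correlation only (adjusted p = 3.52e-09, and adjusted p = 0.14 with an estimated correlation). Among these was HMGCS1 (-0.27). The panel genes LMNB1 (-0.17 ± 0.03) and CYR61 (0.29 ± 0.07) also passed. The 2 h comparison called 334 genes higher and 350 lower, 309 in experiment 1 alone, 174 in experiment 2 alone and 440 without overlapping genes. CYP1B1, TIPARP, PLD6, PRICKLE1 and HMGCS1 overlap genes on the opposite strand.

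By 20 h in 1G, antioxidant genes had risen and genes of the cell cycle, ribosome biogenesis and cornified differentiation had fallen. CYP1A1 (4.81 ± 0.34), CYP1B1 (3.83 ± 0.13), IL24 (2.05 ± 0.17), ALDH3A1 (1.86 ± 0.14), SERPINB2 (1.71 ± 0.14) and heme oxygenase (HMOX1, 1.71 ± 0.15) had the largest increases at a mean log2 CPM of at least 1. Among the largest decreases at that level were ANKRD1 (-1.25 ± 0.10), the tight junction gene CLDN1 (-1.13 ± 0.14), S100A9 (-1.10 ± 0.10), PTX3 (-1.02 ± 0.11) and the integrin ITGB6 (-0.99 ± 0.04, adjusted p = 2.97e-22). Targets of NRF2 rose in 19 of 24 cases and fell in 1, 20 and 1 adjusted over the list alone (adjusted p = 6.33e-36). Examples were SLC7A11 (1.23), TXNRD1 (0.84) and GCLM (0.79). ATF4 targets rose in 13 of 24 and fell in 1, 14 and 1 adjusted over the list alone (adjusted p = 7.16e-10). G2/M genes fell in 28 of 31 cases, 29 adjusted over the list alone (adjusted p = 3.26e-18), and G1/S genes in 25 of 27, 27 adjusted over the list alone (adjusted p = 6.78e-17). Ribosome biogenesis genes fell in 20 of 24, 22 adjusted over the list alone (adjusted p = 9.63e-12). Lower in these 3 lists were CCNB1 (-0.26), MCM4 (-0.26) and UTP20 (-0.24). Genes of keratinocyte-type differentiation fell in 6 of 9 cases, 6 adjusted over the list alone (adjusted p = 1.14e-05), including S100A8 (-1.20), IVL (-0.68) and SLPI (-0.55). Targets of p53 fell in 12 of 25 and rose in 3, 13 and 3 adjusted over the list alone (adjusted p = 0.00414). AGR2 fell by 0.60 on the log2 scale and LMNB1 by 0.23. edgeR called 1571 genes higher and 2026 lower, 2051 in experiment 1 alone, 1483 in experiment 2 alone and 2175 without overlapping genes. The 0 h libraries precede clinostat time in both arms, so these changes hold for cells in 1G that spent longer in doxycycline and in the flask. CYP1B1, ALDH3A1, PTX3 and SLC7A11 overlap genes on the opposite strand.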

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

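The tests of strand overlap and of the sample-sheet number ranges were chosen after the results they bear on had been seen, as were the GC offset as a setting, the splits balanced over the groups and the comparison of line differences by condition.

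The 20 h response differed between lines for 5 genes and was more positive in SUN1L-KDEL cells. The log2 differences were 0.955 for AGR2, 0.575 for TRIB3, 0.41 for SEL1L, 0.402 for ASNS and 0.29 for WARS. In SUN1L-KDEL cells the 4 libraries in simulated microgravity lay above the 4 in 1G for each of them. For TRIB3 the 4 in simulated microgravity lay below the 4 in 1G in GFP-KDEL cells, so its difference came from opposite changes in the lines. All 5 passed with the number ranges as a term (5), with a GC offset (5) and with any 1 of the 16 libraries left out (lowest number 5), which argues against the number ranges, GC content and a single library as the whole cause. WARS overlaps a gene on the opposite strand, and the other 4 passed when such genes were left out, while in each experiment alone edgeR called 0 of 14198 genes (941 and 584 at an unadjusted p under 0.05). Of 100 splits of the 16 libraries, 10 gave as many genes (real 5, highest other 500), so chance cannot be excluded by this count. The 9 others each part the SUN1L-KDEL libraries by gravity in at least 3 of 4 places and so carry that response, a structure of the samples. Over the 34 splits balanced over the groups the highest count was 2. Such splits mix both gravities on each side, which adds the gravity response to the spread and can lower the count, so they cannot decide either. For the difference at 2 h the highest balanced count was 47. A different response of the lines to simulated microgravity, through the LINC complex or through another difference between the lines, may explain the pattern and is open.

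Within groups, libraries separated by their number on the sequencing sample sheet. The first component of the residuals held 21.4% of the residual variance, and 84.9% of it lay between 4 ranges of numbers. The ranges (1 to 10, 11 to 20, 21 to 36 and 37 to 40) are of unequal size and were added after the data were seen. Limits placed on the same libraries can make this share too high. Thinning all libraries to the smallest total left 0.998 of that share and a GC offset left 1, which argues against library size and GC content as the cause. Of the 200 genes that rose most in libraries 21 to 36, 76.5% of those matched to the annotation overlap a gene on the opposite strand, against 39.9% of other genes (Fisher p = 1.89e-17), and the 158 genes whose partner is at least 100 times as abundant shifted by a median of 0.20 on the log2 scale, against -0.00262 over 7890 genes without overlap. Reads from the opposite strand may be part of the cause, but 132 of the 200 genes could be matched, too few for the test, so this cannot be told apart from other differences in how the libraries were made. No biological explanation was tested.

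At 20 h more genes passed in SUN1L-KDEL (970) than in GFP-KDEL cells (250), with 158 against 128 in experiment 1 alone and 169 against 20 in experiment 2 alone, so that most of the excess within experiments lay in experiment 2. The median SD within groups was 1.07 times as large in SUN1L-KDEL cells, so the spread there was not smaller. The fit used 1 estimate of spread per gene for both lines (median standard error 0.0873 in GFP-KDEL and 0.0874 in SUN1L-KDEL cells). The ratio of SDs therefore cannot test why the counts differed. The SUN1L-KDEL count was 2.7 times the GFP-KDEL count with the number ranges as a term and 3.64 times with a GC offset, which argues against both as the whole cause. A stronger response in SUN1L-KDEL cells may explain it, although a ratio of counts is no test of a difference, and the test of the difference itself passed for 5 genes. The mean difference between lines at 20 h was 0.17 over the unfolded protein response list, 0.175 over ATF4 targets, 0.286 over matrix proteases, -0.122 over G1/S genes and -0.127 over G2/M genes.

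Other splits of the same libraries make chance unlikely, without excluding it, for simulated microgravity at 20 h. Only the real split gave as many genes in GFP-KDEL cells (1 of 35, real 250, highest other 67). The same was so in SUN1L-KDEL cells (1 of 35, real 970, highest other 3, the splits that part all 4 pairs of numbers included). It was also so for the lines at 0 h (1 of 35, 800 and 11) and over 3 times (1 of 100, 2173 and 165). Time in 1G at 2 h (1 of 100, 684 and 200) and at 20 h (1 of 100, 3597 and 2179) gave the same picture. With 35 splits the share cannot fall below 1 of 35, and the other splits hold the real differences in their spread. At 2 h the splits say nothing about chance, since the real count was 0 and any split gives as many, in GFP-KDEL cells (35 of 35; real 0, highest other 1), in SUN1L-KDEL cells (35 of 35; 0 and 38) and for the difference (100 of 100; 0 and 47). In edgeR these 3 counts of 0 came with 423, 1036 and 1024 genes at an unadjusted p under 0.05 and with 0 by the DESeq2 test and limma-voom.

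The response differed between 20 h and 2 h for 57 genes in GFP-KDEL cells and for 143 in SUN1L-KDEL cells. With the real split included, 1 of 100 splits gave as many genes in GFP-KDEL cells (highest other 18). In SUN1L-KDEL cells 4 of 100 did (highest other 1229). These shares make chance unlikely without excluding it. The 3 splits with more genes than the real one (1229, 257 and 212) each part the 20 h SUN1L-KDEL libraries wholly by gravity. They therefore carry the 20 h response. Over 28 splits balanced over the groups the highest count was 0 in SUN1L-KDEL cells, but such splits add the gravity response to the spread, which can lower the count. In GFP-KDEL cells the count was 32 without replicate 1 and 35 without replicate 2 in simulated microgravity at 20 h, 36 without replicate 3 in simulated microgravity at 2 h and 30 without replicate 3 in 1G at 20 h. In SUN1L-KDEL cells in simulated microgravity it was 77, 76 and 216 without replicates 1, 2 and 3 at 2 h, and 88 without replicate 3 at 20 h.

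Of 120 group values examined for a library far from the other 3, 5 stood out, where chance gives about 1 in 20. They were AGR2 in GFP-KDEL cells at 0 h (replicate 1 at 5.45 CPM, others 4.57 to 4.69), BIRC3 in GFP-KDEL cells in 1G at 2 h (replicate 2 at 246, others 169 to 179) and in SUN1L-KDEL cells in simulated microgravity at 2 h (replicate 2 at 300, others 244 to 248), CYP1A1 in SUN1L-KDEL cells in 1G at 20 h (replicate 1 at 5.86, others 3.86 to 4.09) and CYP1B1 in SUN1L-KDEL cells in simulated microgravity at 2 h (replicate 3 at 85.3, others 92.2 to 93).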

How the results depend on the processing

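The number ranges, the GC offset, the 2 surrogate variables and the tests without overlapping genes were chosen after the data had been seen.

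Each experiment alone, with fewer libraries, called fewer genes in most comparisons. Experiment 1 alone gave 1 (GFP-KDEL) and 32 (SUN1L-KDEL) for simulated microgravity at 2 h and 39 for their difference, 128 and 158 at 20 h and 0 for the difference, 18 and 42 for the change of the response with time, 451 and 974 for the lines at 0 h and over 3 times and 309 and 2051 for time in 1G at 2 h and 20 h. It shared 1 gene between lines at 2 h and 39 at 20 h, and 10 lists passed in GFP-KDEL cells at 2 h. Experiment 2 alone gave 20 and 169 genes at 20 h and 0 for their difference, 0 and 3 for the change with time, 380 for the lines at 0 h, 174 and 1483 for time in 1G, 15 shared genes at 20 h with a correlation of 0.198, and 0 and 10 lists for the difference at 2 h and 20 h. The counts of 0 are from edgeR, with 941 and 584 genes at an unadjusted p under 0.05 for the difference at 20 h in experiments 1 and 2 and 707 for the change with time in GFP-KDEL cells in experiment 2; the other tools were not run on 1 experiment.

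Without a filter on low counts, edgeR called 23 and 85 genes at 2 h and 63 for their difference, 399 in GFP-KDEL cells at 20 h, 63 for the difference at 20 h (25 higher and 38 lower), and 159 and 284 for the change with time. Nearly all of these genes had been tested before: 2 of the 23, 1 of the 85 and 1 of each 63 had not. The calls at 2 h therefore depend on this setting. Without the filter, the weight of the spread shared between genes (median prior degrees of freedom) went from 12.5 to infinite, also over the genes tested before. For the median gene its own spread then carried no weight, so these calls are no sign of a response hidden by the filter. This setting gave 7 genes shared between lines at 2 h, with a correlation of 0.00368 at 2 h and 0.0363 at 20 h. With the filter the correlation at 2 h was -0.0934 with a jackknife spread of 0.204, so its sign was not determined. The stricter filter gave a correlation of 0.399 at 20 h and 9 lists in GFP-KDEL cells at 2 h.

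With an estimated correlation, the lists past the threshold numbered 0 (GFP-KDEL) and 0 (SUN1L-KDEL) at 2 h and 0 for their difference, 3 and 10 at 20 h and 5 for their difference, 2 and 5 for the change with time, 3 and 6 for the lines, and 2 for time at 2 h. At the preset correlation they were 5, 8, 10, 17, 17, 16, 8, 16, 17, 20 and 11, and fry called 0, 0, 1, 14, 19, 8, 4, 15, 20, 27 and 12.

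The DESeq2 test gave 88 and 244 genes for the change with time, 9 lists in GFP-KDEL cells at 2 h and 13 for the change with time there, where limma-voom gave 14. No experiment term gave 32 and 90 genes for the change with time. A fit of the compared libraries alone gave 157 genes in GFP-KDEL cells at 20 h and 90 for the change with time in SUN1L-KDEL cells.

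The number ranges as a term gave 469 genes in GFP-KDEL cells at 20 h, 104 and 250 for the change with time, 226 shared at 20 h and 10 lists in GFP-KDEL cells at 2 h. With 2 surrogate variables these were 478, 101 and 290, 255 and 8, and the lines at 0 h differed in 1278. The GC offset gave 3 lists in GFP-KDEL cells at 2 h and 17 for the change with time there. Leaving out overlapping genes, a smaller set by construction, gave 158 and 592 genes at 20 h, 37 and 91 for the change with time, 512 and 1385 for the lines, 440 and 2175 for time, 95 shared at 20 h and 5 lists for the difference at 2 h.

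With the combination of experiment and donor as a block, no count of genes moved by more than 1.5 times (241 and 955 at 20 h, 5 for their difference), and 1029 of 1037 values of named genes kept their direction and side of the threshold. This holds for the SUN1L-KDEL response at 20 h as well. There, libraries of the same number correlated in all 4 pairs, although pairing is not shown.

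Over the libraries left out in turn, the genes called ranged from 0 to 0 at 2 h in each line and for the difference, from 149 to 242 (GFP-KDEL) and 590 to 1058 (SUN1L-KDEL) at 20 h and from 5 to 6 for the difference. The change with time ranged from 30 to 60 and 76 to 216, the lines from 512 to 837 and 1947 to 2195, and time from 510 to 758 and 3137 to 3778. Shared genes ranged from 0 to 0 at 2 h and 101 to 157 at 20 h, and correlations from -0.159 to 0.0549 and 0.242 to 0.309. Lists ranged from 2 to 11 (GFP-KDEL) and 5 to 10 (SUN1L-KDEL) at 2 h, 6 to 10 for the difference, 14 to 21 and 14 to 19 at 20 h, 13 to 19 for the difference, 6 to 17 and 11 to 18 for the change with time, 13 to 21 and 18 to 24 for the lines and 9 to 14 and 18 to 20 for time. The libraries that moved a count of genes by more than 1.5 times were, at 20 h, GFP-KDEL replicates 1 and 2 in simulated microgravity (149 and 162) and 3 in 1G (151), SUN1L-KDEL replicate 2 in simulated microgravity (590) and 3 in 1G (622), at 0 h GFP-KDEL replicate 2 (512), and for the change with time those named with its counts above. The correlation at 2 h was 0.0549, within that spread, without SUN1L-KDEL replicate 1 in 1G.

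Among the named genes, experiment 1 alone gave 764 values on the same side, 244 weaker, 19 stronger and 10 moved, and experiment 2 alone 755, 255, 6 and 21.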

Other observations

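The comparison of lines within each condition and the correlations across genes below were computed after the results had been seen.

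Unfolded protein response genes were higher in SUN1L-KDEL cells in each of the 5 conditions, by a mean log2 difference of 0.30 at 0 h, 0.28 at 2 h in 1G, 0.28 at 2 h in simulated microgravity, 0.29 at 20 h in 1G and 0.46 at 20 h in simulated microgravity, where 22 of 26 were higher and 0 lower (adjusted p = 4.87e-08 with an estimated correlation). ATF4 targets differed by 0.20, 0.21, 0.17, 0.21 and 0.38 in the same order. The means of G2/M genes were -0.10, -0.07, -0.08, -0.05 and -0.17, and this list passed with an estimated correlation at 20 h in simulated microgravity (adjusted p = 0.00506) and not in the other 4 conditions (adjusted p = 0.0685, 0.262, 0.203 and 0.552 with an estimated correlation). At 20 h in 1G it did not pass at the preset correlation either (adjusted p = 0.0515), with 0 of 31 members past the threshold in edgeR.

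Across all 14198 genes, the line difference at 0 h correlated with the 20 h response at -0.027 in GFP-KDEL and 0.102 in SUN1L-KDEL cells, with genes not being independent replicates.

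Leukocyte markers were tested because the extraction text speaks of blood mononuclear cells: 5 of 20 passed the filter on low counts, and the list did not pass in any of the 12 comparisons (adjusted p from 0.121 to 0.907). The comparisons are differences between groups, so blood cells present alike in all libraries would not show in them.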
